A study of Mus musculus with 24 samples.

How the data were processed

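Choroid plexus of C57BL mice carrying a humanized ApoE3 or ApoE4 gene, aged 78 weeks, was measured on 24 Affymetrix Mouse430A_2 arrays, 6 for each combination of genotype and diet (normal chow, labelled ND, or a high-fat diet, labelled HFD). Per the labels, replicates 1 to 3 of each group were male and 4 to 6 female. Per the labels' protocols, tissue was fresh-frozen, collected by laser capture microdissection into Trizol, extracted with a Qiagen lipid tissue kit and labelled by in vitro transcription for 24 hours. How the captured regions were chosen, on which dates tissue was taken or arrays were run, and whether each array is a separate animal are not given in the sources used here. The p-values therefore measure the spread between samples. The number of arrays limits the precision.

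The deposited intensity values are the signals that the authors made with GCOS 1.4, per the processing tools in the labels, on a linear scale and scaled array by array to a trimmed mean of about 500. The algorithm and other settings are not given in the sources used here. Each signal was deposited with a detection call by the authors (Present, Marginal or Absent), and the calls were used for a filter. The deposited detection p-values were not used here. The 2 deposited tables held equal signals in 544560 of 544560 cells. Of 22690 probe sets, 64 controls were left out, and of the others 20380 named 1 gene, 691 several genes and 1555 none by the array's annotation. Gene symbols were checked against the reference annotation by Entrez id, which 20351 probe sets matched, and 0 changed.

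Signals were taken to log2 after adding 16. Of the probe sets other than controls, 13936 were Present on at least 6 of 24 arrays and were kept, including some that named several genes or none. Among those of 1 gene, the one with the highest mean stood for its gene, which left 8261 genes of 12393 on the array. Linear models with a mean per group and a term for sex were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend and robust estimation). Contrasts gave 8 comparisons: genotype on each diet, diet in each genotype, their interaction, both averages, and sex. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 passed. Where every array of a group was Absent for a gene, mean signals are given in place of its fold. Array measures (Present share, median signal, hybridization and 3' to 5' controls) were compared by exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

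Gene lists for the cell types and pathways of the tissue, 40 with 888 genes, were written before the data were examined, as were the comparisons, the rule for named genes and most of the alternatives. The 38 lists with at least 5 tested genes, 593 genes in all, were tested with camera in limma at a preset correlation between genes of 0.01, again with the correlation estimated per list, and with fry, which asks whether a list's genes move 1 way on balance. Camera p-values were adjusted over the lists of a comparison. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of 1 list.

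The named genes followed a rule. For each genotype and diet comparison they were the 10 largest rises and 10 largest falls among genes that passed, or the 5 and 5 with the smallest p where fewer than 5 passed. To these came the 4 members with the smallest p in every list that was called or had a member that passed, and always Apoe, Ttr, C1qa, C1qb, C1qc, Irf7 and Trem2. For the interaction and sex, 5 per direction were taken. On simulated data with the spread of these arrays, 10 simulations with 200 changed genes recovered 27.4% of genes changed 1.2-fold, 83% at 1.5-fold and 96.6% at 2-fold, with 8.5 false calls on average. The simulated genes varied independently of each other, without shifts shared by the genes of an array. These numbers therefore need not hold for real arrays, where genes vary together.

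The alternatives tried were a pseudocount of 1 or 64, quantile normalization, no filter or Present on at least 12 arrays, no sex term, the replicate number as a block, only the arrays compared, array weights, all probe sets or their mean per gene, brain marker or epithelial marker means as covariates, and each array left out in turn. Covariates for hybridization controls and for 3' to 5' ratios, and a fit without the 4 arrays of lowest hybridization control signal, were chosen after seeing the data. Those 4 arrays were all ApoE4, replicates 3 and 5 on chow and 2 and 5 on high-fat diet. That fit therefore also had fewer ApoE4 arrays, while no ApoE3 array was left out. The marker means were taken over tested genes, so for a marker gene the covariate holds part of its own value. For each comparison 100 splits of its arrays were also fitted.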

Results

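Gene expression was measured in the choroid plexus, the tissue of the brain ventricles that secretes cerebrospinal fluid, of mice 78 weeks old. The mice carried a humanized ApoE3 or ApoE4 gene, 2 common forms of human apolipoprotein E, the main lipid carrier protein of the brain. They were kept on normal chow or on a high-fat diet. The tissue was taken from frozen brain by laser capture, in which a region of a section is collected under a microscope. The 24 Affymetrix arrays fell into 4 groups of 6, and each group held 3 males and 3 females. No label says that every array came from a separate animal, so the p-values measure the spread between these samples, which can be technical. The deposited signal of each array had a trimmed mean between 500.173 and 500.194, and 8261 genes entered the tests. Values for genes are log2 fold changes ± SE from limma, with Benjamini-Hochberg adjusted p, and n = 6 arrays per group, unless stated otherwise.

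The sex labels were borne out on all 24 arrays. Xist, the transcript of the inactive X chromosome, read 6466.2 to 9598.5 in females and 117.6 to 261.9 in males. The Y-linked gene Eif2s3y read 362.1 to 589.5 in males and 0.9 to 19.2 in females. The genotype labels could not be checked in the same way. The array holds 1 probe set for mouse Apoe, which need not match the human transcript, and it read 1.9 to 7 and was called Absent on 24 of 24 arrays. Ttr, transthyretin, the main secreted protein of the choroid plexus epithelium, was among the brightest genes, at 13080 to 25450. Trem2, a receptor of microglia and other phagocytes, was called Absent on 24 arrays and was not tested.

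The arrays of the 2 genotypes differed in measures that are not about single genes. On chow, 58.2% ± 1.52 (SD, n = 6) of probe sets were called Present in ApoE4 and 54.8% ± 0.574 in ApoE3 (two-sided exact permutation p = 0.00216, the smallest it can give, adjusted p = 0.0144 over 20 such tests). On high-fat diet these shares were 59% ± 1.15 and 55.4% ± 1.76 (exact permutation p = 0.00433, adjusted p = 0.0216). The hybridization controls, transcripts that are normally added in equal amounts to each sample, had a mean log2 signal of 11.54 ± 0.14 in ApoE4 and 11.88 ± 0.13 in ApoE3 on chow (SD, exact permutation p = 0.00216, adjusted p = 0.0144). On high-fat diet it was 11.50 ± 0.31 and 11.85 ± 0.091 (exact permutation p = 0.0195, adjusted p = 0.0649). The log2 3' to 5' ratio of Actb, a measure of RNA quality, was 1.68 ± 0.20 in ApoE4 and 1.98 ± 0.24 in ApoE3 on chow (SD, exact permutation p = 0.0455, adjusted p = 0.13). On high-fat diet it was 1.73 ± 0.17 and 1.84 ± 0.22 (exact permutation p = 0.364, adjusted p = 0.559). That of Gapdh was lower in ApoE4 on both diets (exact permutation adjusted p = 0.226 on chow and 0.206 on high-fat diet). The median signal was lower in ApoE4, at 152.4 ± 8.23 against 168.4 ± 9.14 on chow (SD, exact permutation p = 0.0152, adjusted p = 0.0606) and at 150.6 ± 5.92 against 173.2 ± 4.55 on high-fat diet (exact permutation p = 0.00216, adjusted p = 0.0144), which bears on the numbers of lower and higher genes below. The first principal component of the genes held 26.8% of the variance, and on it the 12 ApoE4 arrays lay on the other side of 0 from the 12 ApoE3 arrays.

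The first comparison asked how the ApoE4 choroid plexus differed from the ApoE3 one on chow. Genes induced by type I interferon were higher in ApoE4. Of the 27 measured members of that list, 20 rose and 0 fell over all genes, and 22 rose and 1 fell, Dhx58 (-0.40 ± 0.14, named after its value was seen), when adjusted over the list alone. Ifit1, an antiviral protein that binds foreign RNA, rose by 2.07 ± 0.24 (a 4.2-fold rise, adjusted p = 3.01e-05). The interferon-induced protease Usp18 rose by 1.77 ± 0.23, the antiviral genes Oasl2 and Ifi27l2a by 1.64 ± 0.22 and 1.53 ± 0.18, and Rtp4 and Ddx60 by 1.47 ± 0.20 and 1.31 ± 0.22. Bst2, or tetherin, rose by 1.27 ± 0.10 (adjusted p = 6.8e-09), Ifitm3, a membrane protein that blocks virus entry, by 0.92 ± 0.11, and Irf7, the transcription factor that amplifies the type I interferon response, rose 2.3-fold (adjusted p = 0.000533). Oas1a, an RNA-sensing synthetase, was Absent on all 6 ApoE3 arrays and higher in ApoE4 (mean signal 374.5 ± 124.7 in ApoE3 and 915.7 ± 109.3 in ApoE4, SD, limma adjusted p = 5.73e-05). The list as a whole had a median of 0.78 (camera adjusted p = 5.82e-27, and adjusted p = 0.0438 with an estimated correlation), and 6 of 6 ApoE4 arrays lay above every ApoE3 array. Of 47 list calls in 7 comparisons this was the 1 that held with an estimated correlation. With fry, which tests a list without comparing it with other genes, 11 of the 47 held, this one among them.

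**Figure D1:**
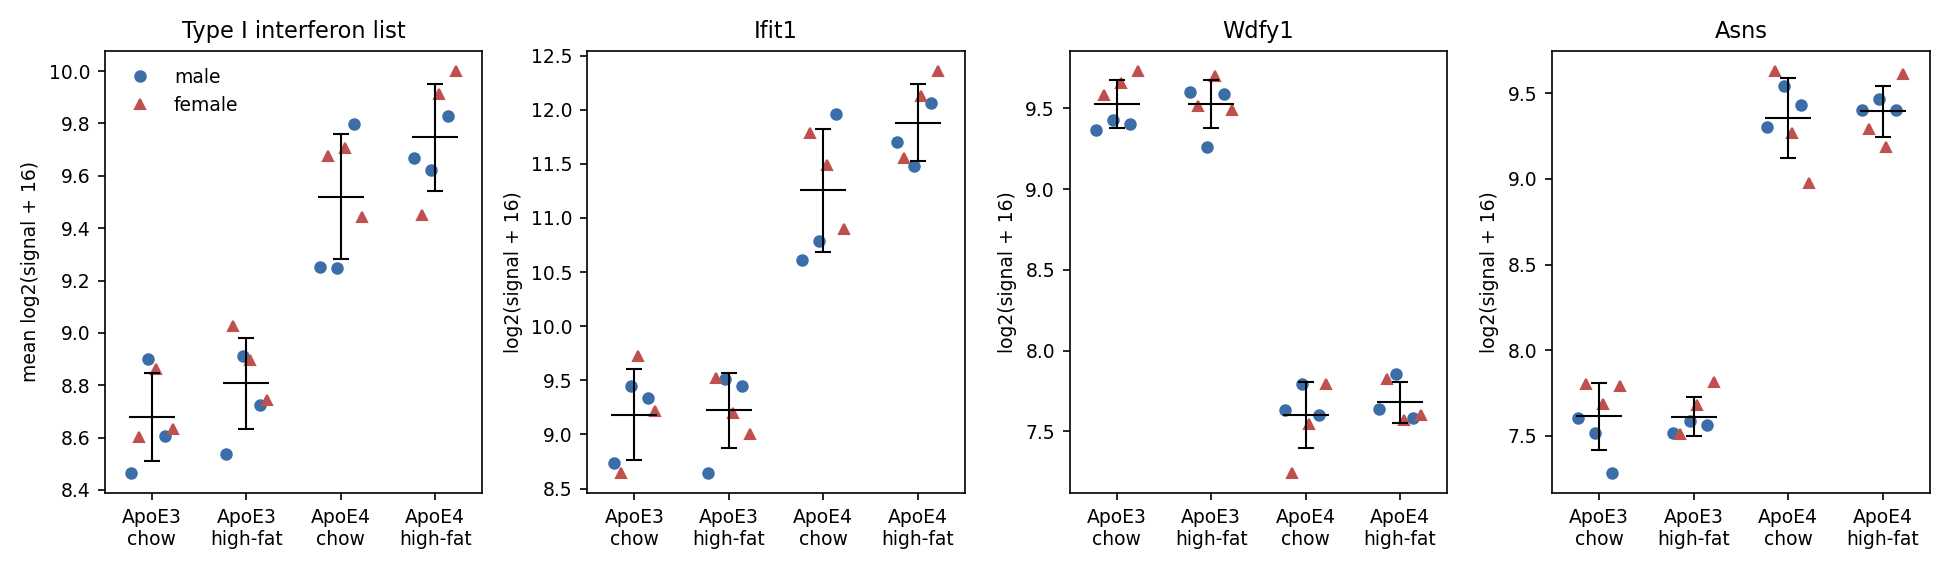
Log2(signal + 16) per array of the mean of the type I interferon list, Ifit1, Wdfy1 and Asns in the 4 groups, with males as circles, females as triangles and bars for the mean ± SD (n = 6). In each panel the 12 ApoE4 arrays are apart from the 12 ApoE3 arrays, and mean Ifit1 signals were 586 and 2588 on chow and 595.1 and 3849 on high-fat diet in ApoE3 and ApoE4.

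Genes of the interferon gamma list were mixed. Over all genes 4 of its 13 members rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. The GTPases Gbp3 (1.66 ± 0.24), Irgm1 (0.83 ± 0.17), Gbp7 (0.82 ± 0.19) and Irgm2 (0.74 ± 0.20) were the ones that rose. The transcription factors Irf1 (-0.50 ± 0.14) and Irf8 (-0.50 ± 0.14) fell, and they are named here after their values were seen. The list's median was 0.48 (camera adjusted p = 0.0223, and adjusted p = 0.702 with an estimated correlation). Of 11 MHC class I genes, B2m, the light chain of the complex, rose by 0.47 ± 0.11 (adjusted p = 0.00977) and the proteasome activator Psme1 by 0.22 ± 0.070 (adjusted p = 0.0417). The other 9 did not pass (list median 0.17, camera adjusted p = 0.0452, and adjusted p = 0.702 with an estimated correlation). The calls of the interferon gamma and class I lists ended with fry and in 3 fits chosen after seeing the data, those with the hybridization controls or the 3' to 5' ratio as a covariate and the one without the 4 arrays of lowest hybridization control signal. The class I call also ended with a pseudocount of 64.

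The gene with the smallest adjusted p among those that rose was Asns, asparagine synthetase, a target of the amino acid stress response. It was Absent on all 6 ApoE3 arrays and higher in ApoE4 (mean signal 181 ± 25.6 in ApoE3 and 647 ± 103 in ApoE4, SD, n = 6, limma adjusted p = 1.11e-12). Other members of the unfolded protein response list did not follow as a group: Pdia6 rose by 0.55 ± 0.12, 2 of 22 rose in all, and the list was not called (median 0.090, camera adjusted p = 0.0786). The largest falls were those of Wdfy1, an adaptor of Toll-like receptor signalling, at -1.93 ± 0.095 (a 3.8-fold fall, adjusted p = 3.18e-14), and of the zinc finger gene Zfp386, at -1.61 ± 0.087 (adjusted p = 1.84e-13). For Asns, Wdfy1 and Zfp386, 6 of 6 ApoE4 arrays lay beyond every ApoE3 array.

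Camera called 3 cell type lists lower in ApoE4 on chow, those of macrophages, of T and NK cells and of smooth muscle. Among 20 macrophage and microglia genes 0 rose and 3 fell, and 7 fell when adjusted over the list alone. The scavenger receptor Stab1 fell (-0.82 ± 0.14), as did Itgb2, an integrin of leukocytes (-0.53 ± 0.14). Cd163 passed as well, but it was Absent on the 6 arrays of both groups and no fold is given. The list's median was -0.12 (camera adjusted p = 0.0223, and adjusted p = 0.702 with an estimated correlation). The myeloid genes Gpr33 (-1.11 ± 0.21), Dok2 (-1.07 ± 0.20) and Cd300lf (-0.94 ± 0.25) were among the largest falls, and the lectin receptor Clec4d was Absent on 6 ApoE4 arrays and lower there (mean signal 99 ± 7.8 in ApoE3 and 43.2 ± 17.6 in ApoE4, SD). In the smooth muscle and pericyte list 5 of 12 genes fell, and 7 did when adjusted over the list alone. They included the contractile genes Tpm2 (-0.55 ± 0.11), Tagln (-0.57 ± 0.15) and Acta2 (-0.32 ± 0.10) and the receptor Notch3 (-0.36 ± 0.11) (list median -0.34, camera adjusted p = 0.0118, and adjusted p = 0.569 with an estimated correlation). The NK cell receptor Klrd1 fell by 0.69 on the log2 scale and was the 1 of 6 T and NK cell genes that passed (list median -0.34, camera adjusted p = 0.0452, and adjusted p = 0.569 with an estimated correlation), a list call that quantile normalization ended (T and NK cells, camera adjusted p = 0.212). With the brain marker mean as a covariate none of these 3 lists was called, fry ended the macrophage call, and the T and NK cell call ended without the 4 arrays of lowest hybridization control signal. Without ApoE3 chow array 4 the smooth muscle and macrophage lists were not called. Brain cell lists were not called on chow, with medians of -0.19 for neurons, -0.27 for myelin genes and -0.058 for astrocytes (camera adjusted p = 0.162, 0.223 and 0.867).

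Other genes changed singly on chow. The gamma-secretase subunits Psenen (-0.32 ± 0.057) and Aph1a (-0.43 ± 0.079), parts of the enzyme that cleaves the amyloid precursor protein, fell, and the lipid transporters Abca7 (-0.46 ± 0.082) and Abcg4 (-0.42 ± 0.12) fell. The metallothionein genes Mt1 (-0.38 ± 0.12) and Mt2 (-0.47 ± 0.11) fell. Of 13 clock genes, the output genes Dbp (-1.05 ± 0.27) and Tef (-0.65 ± 0.15) and the repressor Per3 (-0.65 ± 0.16) fell while the activator Arntl rose (0.80 ± 0.22). The lists of these genes were not called: camera adjusted p was 0.247 for amyloid processing, 0.266 for lipid efflux, 0.869 for oxidative stress defence and 0.066 for the clock. Of the complement genes, C1qa passed (adjusted p = 0.02) and was Absent on all 6 ApoE3 arrays (mean signal 293.6 ± 84 in ApoE3 and 398.9 ± 69.9 in ApoE4, SD). The probe set used for C1qb was at -0.56 ± 0.25 (adjusted p = 0.154), while another of its probe sets read higher on average in ApoE4. C1qc was at 0.22 ± 0.16 (adjusted p = 0.364). Ttr was at 0.0014 ± 0.13 (adjusted p = 0.996), and of 23 epithelial genes 1, the copper transporter Slc31a1, passed (-0.21 ± 0.065). Other probe sets of Gbp7, Pdia6 and Slc31a1 were at -0.11, -0.021 and 0.031 and did not pass (adjusted p = 0.829, 0.931 and 0.728), so these 3 results rest on 1 probe set each.

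In all, 805 of 8261 genes passed on chow, 342 higher and 463 lower in ApoE4, and 172 of them changed at least 1.5-fold. After quantile normalization 554 passed, 293 higher and 261 lower, so the share of higher genes depended on the scaling. The count was 514 with only the 12 arrays compared and 1375 with the hybridization controls as a covariate, a fit chosen after seeing the data, and with 1 array left out it was 525 and 522 without ApoE3 chow array 1 or 2 and 515, 488 and 488 without ApoE4 chow array 1, 2 or 4.

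On the high-fat diet the same question was asked of the other 12 arrays. Interferon-induced genes were again higher in ApoE4: 23 of 27 type I genes rose over all genes, and 23 rose and 1 fell when adjusted over the list alone. Ifit1 rose by 2.66 ± 0.24 (a 6.31-fold rise, adjusted p = 7.8e-07), Ifit3 by 2.37 ± 0.31, Usp18 by 2.15 ± 0.23, Oasl2 by 2.07 ± 0.22 and Ddx60 by 1.98 ± 0.22. The RNA sensor Ifih1 rose by 1.04 ± 0.11, the antiviral enzyme Rsad2 by 1.29 ± 0.14, Bst2 by 1.19 ± 0.10 and Irf7 by 1.37 ± 0.19 (adjusted p = 4.12e-05). The list's median was 0.80 (camera adjusted p = 3.21e-22, and adjusted p = 0.0983 with an estimated correlation), and 6 of 6 ApoE4 arrays lay above every ApoE3 array. In the interferon gamma list 7 of 13 genes rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone. Gbp3 rose by 1.82 ± 0.24, Irgm1 by 1.04 ± 0.17 and Gbp7 by 0.93 ± 0.19 (list median 0.86, camera adjusted p = 0.00184, and adjusted p = 0.766 with an estimated correlation). B2m rose by 0.58 ± 0.11, Psme1 by 0.30 ± 0.070 and H2-K1, a class I heavy chain, by 0.26 ± 0.093, but the class I list was not called (median 0.21, camera adjusted p = 0.0767).

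Asns was again Absent on all 6 ApoE3 arrays and higher in ApoE4 (mean signal 180.4 ± 16.4 in ApoE3 and 659.6 ± 69.1 in ApoE4, SD, limma adjusted p = 7.64e-13). Wdfy1 was at -1.85 ± 0.095 (a 3.6-fold fall, adjusted p = 9.53e-14) and Zfp386 at -1.49 ± 0.087 (adjusted p = 7.64e-13). Ribosomal protein genes were slightly higher: 5 of 26 rose and 0 fell, among them Rplp0 (0.34 ± 0.070) and Rps3 (0.28 ± 0.065). Their median was 0.097 (camera adjusted p = 0.00269, and adjusted p = 0.766 with an estimated correlation), a direction and call that quantile normalization left in place and a call that fry ended. On chow the ribosomal list was not called, and its mean lay above the ApoE3 mean on 3 of 6 ApoE4 arrays. Pcna, the clamp of DNA polymerase, rose by 0.43 ± 0.075, and the lysosomal enzyme Gla by 0.53 ± 0.091, while the lists of cell cycle (camera adjusted p = 0.852) and lysosome genes (camera adjusted p = 0.852) were not called.

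Genes of brain cells were among the largest falls in ApoE4 on high-fat diet. They included the neurofilament gene Nefh (-1.19 ± 0.33), the metallothionein Mt3 (-1.12 ± 0.13) and the glutamate receptor subunit Gria2 (-1.12 ± 0.18). Malat1, a nuclear long noncoding RNA, fell as well (-1.34 ± 0.32). In the myelin list 6 of 10 genes fell and 1 rose, with Mbp at -1.05 ± 0.17 (adjusted p = 0.000204), Mobp at -0.94 ± 0.20 and Sox10 at -0.54 ± 0.13. The list's median was -0.51 and it was not called (camera adjusted p = 0.0903). The medians of the neuron and astrocyte lists were -0.22 and -0.11 (camera adjusted p = 0.682 and 0.783). Over all 24 arrays the mean log2 signal of these 3 brain marker lists was 8.03 in ApoE4 and 8.22 in ApoE3.

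Single macrophage, vascular and gamma-secretase genes fell as well, in lists that were not called. Stab1 (-0.86 ± 0.14) and F13a1, a coagulation factor of tissue macrophages (a 2-fold fall), fell. In their list 7 of 20 macrophage genes fell and 0 rose, and the list was not called (median -0.14, camera adjusted p = 0.283). In the smooth muscle list 6 of 12 genes fell, including Acta2 (-0.43 ± 0.10), Des (-0.52 ± 0.13) and Myh11 (-0.50 ± 0.15) (median -0.31, camera adjusted p = 0.0767). Of the gamma-secretase genes, 4 fell: Psenen (-0.43 ± 0.057), Aph1a (-0.30 ± 0.08, named after its value was seen), Psen2 (-0.57 ± 0.12) and Ncstn (-0.70 ± 0.16). In the amyloid precursor processing and clearance list 7 of 15 genes fell, and the list was not called (camera adjusted p = 0.11) except after quantile normalization (adjusted p = 0.0148). The fall of Aplp2 (-0.27 ± 0.056) is uncertain, because another of its probe sets rose by 0.61 and passed. The inflammatory genes Il1b (-0.53 ± 0.12), Icam1 (-0.52 ± 0.12) and Ccl8 (-0.64 ± 0.22) fell, as 5 of 14 in their list did, with no call of the list (camera adjusted p = 0.11). The iron hormone gene Hamp (-0.90 ± 0.29) and the cholesterol synthesis gene Dhcr7 (-0.61 ± 0.14) fell.

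In all, 2302 of 8261 genes passed on high-fat diet, 892 higher and 1410 lower in ApoE4, and 294 of them changed at least 1.5-fold. After quantile normalization 1615 passed, 828 higher and 787 lower. With the brain marker mean of each array as a covariate 1221 passed.

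The effects of genotype on the 2 diets were then set side by side. Across 8261 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.699, and the 2 comparisons share no array. On both diets 204 genes rose, where 36.9 would from independent lists, and 283 fell, where 79 would. The 1 gene called in opposite directions was Dnajb2, a chaperone, named after its values were seen (0.24 ± 0.076 on chow and -0.23 ± 0.076 on high-fat diet). Averaged over diets, with 12 arrays per genotype, 3146 genes passed, 1205 higher and 1941 lower in ApoE4, and 196 of them changed at least 1.5-fold. After quantile normalization 2401 passed, 1222 higher and 1179 lower.

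**Figure D2:**
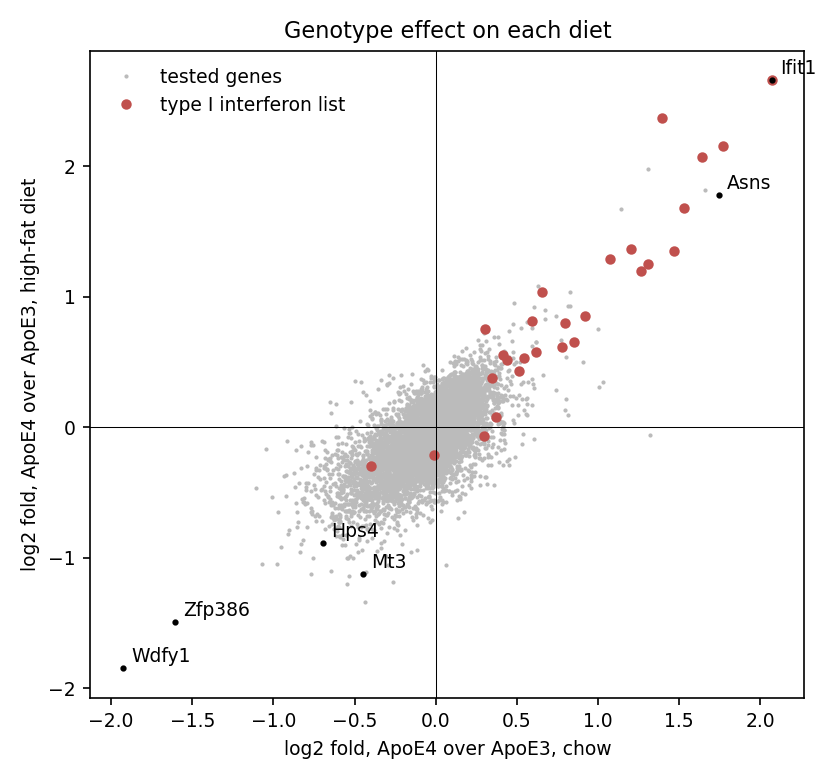
Log2 fold change of ApoE4 over ApoE3 on chow (horizontal) and on high-fat diet (vertical), 1 point for each of 8261 genes, with the type I interferon list in red and 6 named genes labelled. Most interferon genes and Asns lie at the upper right, and Wdfy1 and Zfp386 at the lower left.

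The averaged comparison called 23 of 27 type I interferon genes up and 1 down (median 0.75, camera adjusted p = 3.11e-24, and adjusted p = 0.0691 with an estimated correlation). The interferon gamma list had a median of 0.72 (camera adjusted p = 0.00546, and adjusted p = 0.639 with an estimated correlation). The class I list had a median of 0.18 (camera adjusted p = 0.0367, and adjusted p = 0.639 with an estimated correlation), and ribosomal protein genes one of 0.063 (camera adjusted p = 0.0367, and adjusted p = 0.79 with an estimated correlation). Smooth muscle genes were lower, with 8 of 12 down (median -0.36, camera adjusted p = 0.0222, and adjusted p = 0.639 with an estimated correlation). The brain marker covariate ended the smooth muscle and ribosomal calls, and the ribosomal call also ended with quantile normalization, with fry and without any 1 of 8 arrays. The class I call ended with the hybridization or 3' to 5' covariate and without the 4 arrays of lowest hybridization control signal, and the interferon gamma call with the hybridization covariate. Genes of the epithelium itself changed by small amounts. The folate receptor Folr1 rose by 0.17 ± 0.045 and the anti-aging hormone Kl, or Klotho, fell by 0.19 on the log2 scale. In their list 1 of 23 genes rose and 5 fell, and the list was not called (median -0.030, camera adjusted p = 0.802). Of 21 genes of cerebrospinal fluid secretion, the anion exchanger Slc4a2 fell (-0.23 ± 0.054) and the carbonic anhydrase Car2 rose (0.17 ± 0.045), and the list was not called (camera adjusted p = 0.981). Among lipoprotein receptors, Lrp2 (-0.44 ± 0.12) and Sort1 (-0.15 ± 0.045) fell, and Abca7 fell (-0.49 ± 0.058). Enzymes of fatty acid oxidation such as Decr1 (0.24 ± 0.045) and Etfdh (0.23 ± 0.046) rose, and 7 of 22 members of that list rose and 3 fell (camera adjusted p = 0.176). Under the brain marker covariate the averaged count was 1781.

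The next comparison asked what a high-fat diet changed in ApoE3 mice. It called 19 genes, all of them higher on high-fat diet. The long noncoding RNAs Meg3 (0.81 ± 0.15, a 1.75-fold rise) and Neat1 (0.78 ± 0.15) and the myelin gene Mbp (0.80 ± 0.17) rose most. Mylip, a ligase that marks the LDL receptor for degradation and is induced by the sterol sensor LXR, rose by 0.42 ± 0.083 (adjusted p = 0.0296), and for Meg3, Mbp and Mylip 6 of 6 high-fat arrays lay above every chow array. The RNA-processing genes Pan2 (0.51 ± 0.095) and Pabpn1 (0.43 ± 0.086) and the deacetylase Sirt7 (0.42 ± 0.085) rose too. In the myelin list Mbp alone of 10 genes passed over all genes, 3 rose when adjusted over the list alone, and its median was 0.17 (camera adjusted p = 0.0114, and adjusted p = 0.771 with an estimated correlation). The median of the neuron list was 0.17 (camera adjusted p = 0.339). The ApoE3 high-fat arrays also enter the fall of Mbp in ApoE4 on high-fat diet, so these results on Mbp are not independent.

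No ribosomal protein gene and no cholesterol synthesis gene passed singly in ApoE3, but both lists shifted down. The ribosomal list had a median of -0.10, with 24 of 26 members lower (camera adjusted p = 5.34e-06, and adjusted p = 0.771 with an estimated correlation). This call and the ribosomal call for genotype on high-fat diet share the ApoE3 high-fat arrays. The cholesterol list had a median of -0.095 (camera adjusted p = 0.00753, and adjusted p = 0.771 with an estimated correlation), with the sterol enzymes Sc5d at -0.26 ± 0.079 and Msmo1 at -0.33 ± 0.11. Adjusted over the list alone, 2 cholesterol genes and 0 ribosomal genes fell. The lipogenic regulator Srebf1 was at 0.32 ± 0.086 (adjusted p = 0.0798), and the lipid transporter Abca1 at 0.23 ± 0.098 (adjusted p = 0.303). Fry ended the calls of all 3 lists, and the brain marker mean as a covariate that of the cholesterol list. Mbp, 1 of the 19 genes called, is itself part of the brain marker mean. The count of 19 was 0 with the brain marker mean as a covariate and 107 with array weights. With 1 array left out, it was 0 without ApoE3 chow array 1, 3 or 5 or high-fat array 1, it was 3, 5 and 7 without ApoE3 high-fat arrays 2, 4 and 6, and it was 74 without ApoE3 chow array 2, which also ended the calls of the cholesterol and myelin lists.

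In ApoE4 mice the high-fat diet called 0 genes by limma, with 576 at an unadjusted p under 0.05. The smallest p-values among genes with higher values were those of Cd163, a hemoglobin scavenger receptor of macrophages (mean signal 19 on chow and 46.2 on high-fat diet, adjusted p = 0.176), Wee1, a kinase that holds back cell division (0.70 ± 0.14, adjusted p = 0.176), the glucocorticoid-induced genes Fkbp5 (0.60 ± 0.13, adjusted p = 0.246) and Sgk1 (0.29 ± 0.065, adjusted p = 0.251), and the apolipoprotein gene Apod (0.70 ± 0.15, adjusted p = 0.251). Among genes with lower values they were those of the endoplasmic reticulum proteins Sdf2l1 (-0.60 ± 0.15) and Pdia3 (-0.36 ± 0.097). Cd163 was Absent on all 6 chow arrays, so no fold is given.

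**Figure D3:**
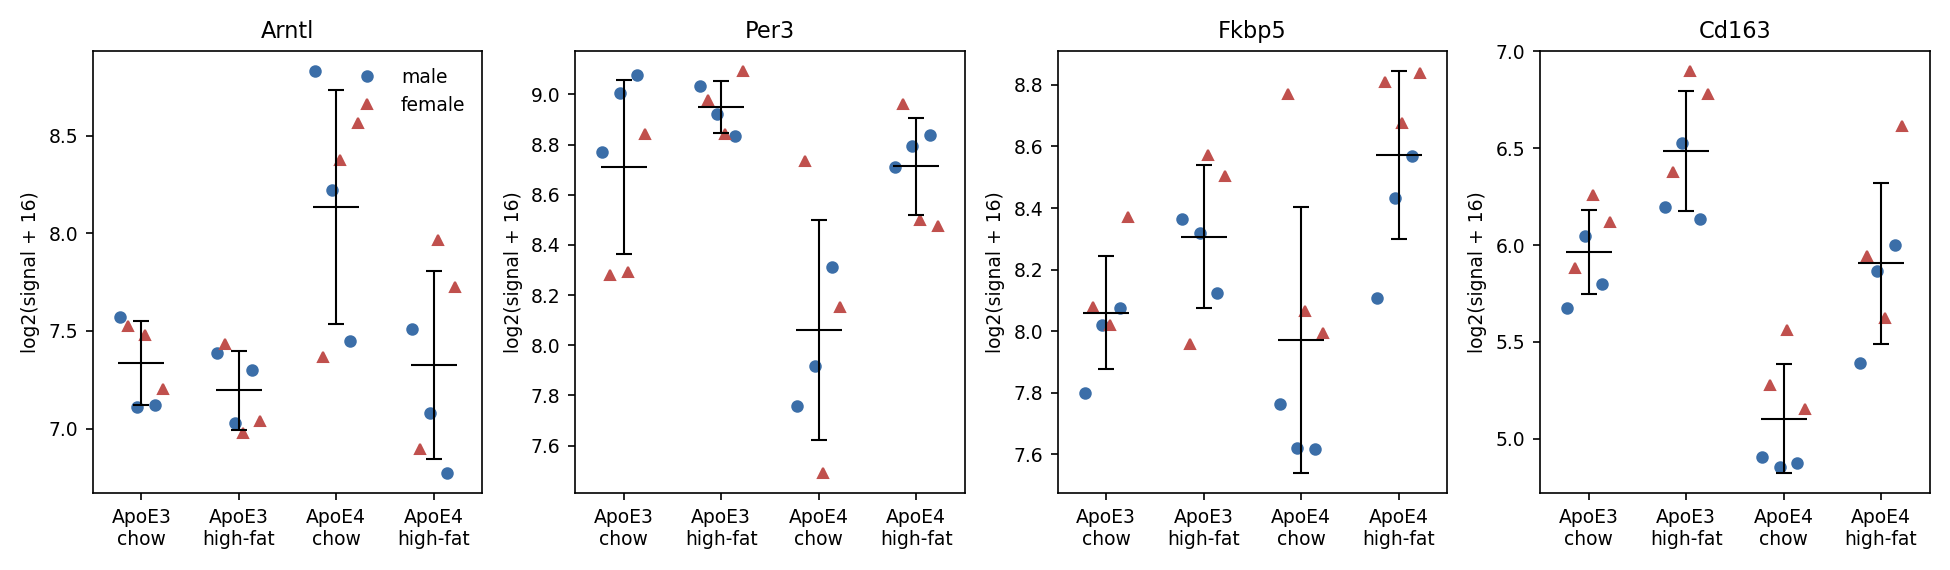
Log2(signal + 16) per array of Arntl, Per3, Fkbp5 and Cd163 in the 4 groups, with males as circles, females as triangles and bars for the mean ± SD (n = 6). In ApoE4 the mean signal on chow and on high-fat diet was 285 and 152 for Arntl, 262 and 407 for Per3, and 246 and 370 for Fkbp5, none of which passed over all genes. In ApoE3 the Arntl means were 147 and 132, so that for Arntl ApoE4 on chow is the group apart.

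Several gene lists nevertheless shifted in ApoE4 on high-fat diet, by camera with a preset correlation, and none of the 14 was called with an estimated one or with fry. Glucocorticoid targets were higher (median 0.23, camera adjusted p = 9.01e-06, and adjusted p = 0.109 with an estimated correlation), and 5 of 10 rose when adjusted over the list alone. Clock genes had a median of 0.38 (camera adjusted p = 0.000275, and adjusted p = 0.11 with an estimated correlation), and adjusted over the list alone 7 of 13 rose and 2 fell. Per2 was at 1.24 ± 0.34, Per3 at 0.65 ± 0.16, Hlf at 0.38 ± 0.091 and Arntl at -0.81 ± 0.22, with adjusted p over all genes of 0.445, 0.335, 0.327 and 0.415. The type I interferon list had a median of 0.21 (camera adjusted p = 1.52e-07, and adjusted p = 0.363 with an estimated correlation), and 1 of 27 rose when adjusted over the list alone. Macrophage genes had a median of 0.17 (camera adjusted p = 0.000275, and adjusted p = 0.415 with an estimated correlation), with 1 of 20 up over the list alone.

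Genes of the unfolded protein response were lower in ApoE4 on high-fat diet (median -0.16, camera adjusted p = 0.000275, and adjusted p = 0.35 with an estimated correlation), and 4 of 22 fell when adjusted over the list alone. Enzymes of fatty acid oxidation had a median of -0.071 (camera adjusted p = 0.00815, and adjusted p = 0.242 with an estimated correlation), heat shock genes one of -0.092 (camera adjusted p = 0.0339, and adjusted p = 0.7 with an estimated correlation) and cholesterol synthesis genes one of -0.065 (camera adjusted p = 0.0473, and adjusted p = 0.728 with an estimated correlation). LXR targets had a median of 0.073 (camera adjusted p = 0.0144, and adjusted p = 0.109 with an estimated correlation), with 2 of 14 up over the list alone. The lists of neurons (median 0.10, camera adjusted p = 0.00815, and adjusted p = 0.415 with an estimated correlation), MHC class I (0.11, camera adjusted p = 0.0144, and adjusted p = 0.593 with an estimated correlation) and interferon gamma (0.18, camera adjusted p = 0.0193, and adjusted p = 0.714 with an estimated correlation) were higher. Oxidative stress defence had a median of 0.044 (camera adjusted p = 0.0417, and adjusted p = 0.415 with an estimated correlation) and cerebrospinal fluid secretion one of -0.049 (camera adjusted p = 0.0417, and adjusted p = 0.7 with an estimated correlation). The brain marker covariate ended the fluid secretion, class I, interferon gamma, heat shock, cholesterol and LXR calls, and the hybridization covariate those of fluid secretion, heat shock and cholesterol. The 3' to 5' covariate ended the cholesterol call. Without the 4 arrays of lowest hybridization control signal the unfolded protein response, fatty acid oxidation, heat shock, oxidative stress and fluid secretion lists were not called. All 4 are ApoE4 arrays, so both groups compared were smaller in that fit. Whether the smaller groups or the weaker control signal ended these calls was not tested. The gene count was 12 with the brain marker covariate, 5 without ApoE4 chow array 4 and 1 without ApoE4 high-fat array 4.

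**Figure D4:**
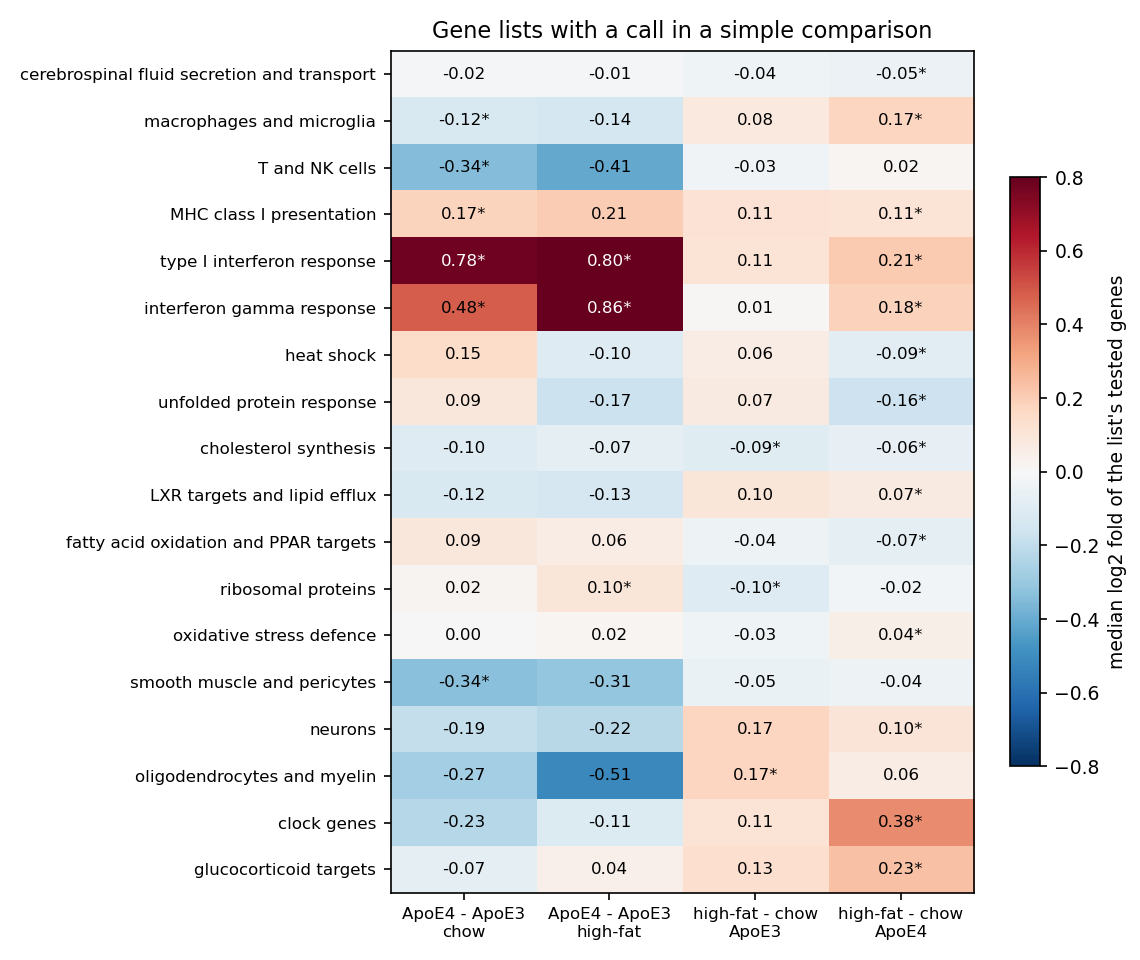
Median log2 fold change of the measured members of 18 gene lists in the 4 simple comparisons, with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The interferon lists are highest in ApoE4 on both diets, and most diet shifts are under 0.2 in size.

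Whether the diet acted differently in the 2 genotypes was tested directly. The interaction called 0 genes by limma, with 835 at an unadjusted p under 0.05. Neat1 had the smallest p, at -1.12 ± 0.22 (adjusted p = 0.146), and Wee1 was at 0.80 ± 0.20 (adjusted p = 0.204). The diet effects in ApoE3 and ApoE4 correlated with r = 0.0328 across genes. The unfolded protein response list differed (median -0.22, camera adjusted p = 0.00686, and adjusted p = 0.981 with an estimated correlation), as did ribosomal protein genes (median 0.084, camera adjusted p = 0.00845, and adjusted p = 0.981 with an estimated correlation). In neither list did a gene pass over all genes. Fry ended both calls, the fit without the 4 arrays of lowest hybridization control signal that of the unfolded protein response, and quantile normalization that of the ribosomal proteins (camera adjusted p = 0.235). The gene count was 2 with the epithelial marker covariate and 1 without ApoE4 chow array 5 or ApoE3 high-fat array 5. The ribosomal calls of the interaction, of genotype on high-fat diet and of diet in ApoE3 share the ApoE3 high-fat arrays. They are not separate results. For genotype on chow and for diet in ApoE4 the ribosomal list was not called. In each of those, 3 of 6 arrays lay beyond the other group's mean in the direction of the shift.

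Averaged over genotypes, the high-fat diet called 3 genes, all higher. Mylip rose by 0.35 ± 0.059 (adjusted p = 0.0158), and Apod, an apolipoprotein that binds small lipids, by 0.63 ± 0.11 (adjusted p = 0.0222). Cd163 passed too (adjusted p = 0.0182) but was Absent on all 12 chow arrays, with mean signals on chow and high-fat diet of 47 and 75.4 in ApoE3 and 19 and 46.2 in ApoE4. At an unadjusted p under 0.05 there were 881. Srebf1 was next, at 0.30 ± 0.061 (adjusted p = 0.0526), and the lipid transporter Abca1 was at 0.25 ± 0.069 (adjusted p = 0.177). LXR targets as a list had a median of 0.049, with 4 of 14 up when adjusted over the list alone (camera adjusted p = 0.00367, and adjusted p = 0.065 with an estimated correlation). Cholesterol synthesis genes were lower, with 17 of 18 below 0 (median -0.074, camera adjusted p = 0.000184, and adjusted p = 0.418 with an estimated correlation). Glucocorticoid targets were higher (median 0.16, camera adjusted p = 1.04e-05, and adjusted p = 0.065 with an estimated correlation), and 5 of 10, Fkbp5 among them at 0.42 ± 0.093, rose when adjusted over the list alone. Of 20 macrophage genes 4 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.000184, and adjusted p = 0.418 with an estimated correlation). Of the C1q genes C1qc was at 0.41 ± 0.11 (adjusted p = 0.164), and C1qa did not pass (adjusted p = 0.328).

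The other lists shifted by diet in the average are given together. Type I interferon (0.18, camera adjusted p = 7.34e-07), myelin (0.13, camera adjusted p = 0.00166), clock (0.23, camera adjusted p = 0.00367), MHC class I (0.11, camera adjusted p = 0.0063) and neuron genes (0.16, camera adjusted p = 0.00656) were higher. With an estimated correlation the adjusted p of these 5 lists was 0.418, 0.24, 0.24, 0.418 and 0.418. Ribosomal protein (-0.062, camera adjusted p = 4.58e-05), fatty acid oxidation (-0.084, camera adjusted p = 0.00102), fluid secretion (-0.035, camera adjusted p = 0.0142), epithelium (-0.027, camera adjusted p = 0.0463) and fibroblast genes (-0.077, camera adjusted p = 0.0495) were lower. With an estimated correlation the adjusted p of these 5 was 0.418, 0.121, 0.467, 0.635 and 0.685. The count of 3 genes rose to 38 with the brain marker covariate and to 24 with array weights, and with 1 array left out it was 2 to 15, with 15 without ApoE3 chow array 2 and 14 without ApoE4 chow array 4. Of the 14 list calls of this comparison fry left 2, those of LXR and glucocorticoid targets. Quantile normalization ended the calls of the fluid secretion, epithelium and fibroblast lists, and the brain marker covariate those of epithelium, fluid secretion, macrophages, class I and cholesterol. The epithelium call also ended with the hybridization or 3' to 5' covariate, and the fibroblast call with the replicate block, without the 4 arrays of lowest hybridization control signal and without any 1 of 17 arrays.

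Sex was compared last, over 12 female and 12 male arrays. It called 106 genes, 68 higher and 38 lower in females. Xist (5.43 ± 0.091) and the Y-linked genes Uty (-3.54 ± 0.12) and Kdm5d (-2.58 ± 0.11) changed most, and Eif2s3y, which passed too, was Absent on all 12 female arrays, so no fold is given. Of other genes, the carboxypeptidase-like gene Cpxm2 rose by 1.16 ± 0.072 (adjusted p = 2.59e-12) in females, the protease inhibitor A2m by 0.98 ± 0.10, the proteoglycan Bgn, which lies on the X chromosome, by 0.97 ± 0.077 and the adhesion gene Cdh1 by 0.94 ± 0.11. The defensin gene Defb9 (-0.60 ± 0.10) and Neat1 (-0.47 ± 0.11) were lower in females. The count was 51 without the 4 arrays of lowest hybridization control signal, a fit chosen after seeing the data.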

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

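Among the tests of this part, the time-of-day test, the immune cell test and the fits that let sex change an effect were chosen only after the result was seen.

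Interferon-induced genes were higher in ApoE4 on both diets. The values do not show more immune cells in the ApoE4 tissue. The macrophage and microglia list had a median of -0.137 averaged over diets, against 0.75 for the type I interferon list. Its bootstrap 95% interval, -0.359 to -0.027, resamples 20 genes and holds no spread between arrays. The list mean lay under the ApoE3 mean on 5 of 6 ApoE4 arrays on chow and on 6 of 6 on high-fat diet. Camera did not call the list in the averaged comparison. It mixes macrophage and microglia genes, so it does not separate immune cells of the tissue from captured brain. The values argue against a few arrays with a strong interferon response, since 12 of 12 ApoE4 arrays lay above every ApoE3 array of the same diet. With the brain marker mean or the hybridization controls as a covariate the list's median stayed at 0.77 (type I interferon response, averaged over diets). A response of the tissue to ApoE4 may underlie the pattern, as a hypothesis found and tested on the same arrays, and a difference between the mouse colonies, such as housing or an infection, or a linked genome segment stays open as untested.

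The genotypes also differed broadly, with 3146 genes called in the averaged comparison and lower hybridization controls in ApoE4 (mean log2 signal 11.52 against 11.87). The controls were read after each array was scaled, so a lower value need not mean weaker hybridization. With the hybridization control signal as a covariate 2798 genes were called, 2264 of them among the 3146. With the 3' to 5' ratio as a measure of RNA quality 2781 were called, 2500 of them shared. Most of the 3146 thus stayed called with either measure in the fit. Each measure had a different mean in the 2 genotypes (for the ratio, 0.72 in ApoE4 and 0.89 in ApoE3). These fits therefore cannot exclude array hybridization strength or RNA quality as a cause. Neighbouring brain tissue in the captured samples cannot be told apart from genotype. With the brain marker mean as a covariate 1781 genes were called, 1661 of them shared, while the median size of the log2 change of the genes called went from 0.27 to 0.25 and its SE from 0.0705 to 0.0867, and the brain marker mean itself was 8.03 in ApoE4 and 8.22 in ApoE3. Linked genome segments that differ between the 2 mouse lines cannot be told apart either, since 75 of 171 called genes changed at least 1.5-fold, counted without the interferon and MHC lists and among genes of known position, had a neighbouring gene called in the same direction, above the median of 67 in 1000 shuffles and under the upper end of their 95% range, 80, and an effect of ApoE4 itself stays open as untested.

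In ApoE4, the clock and glucocorticoid target lists were called shifted on high-fat diet by camera, while 0 genes passed by limma and neither call held with an estimated correlation (adjusted p = 0.11 and 0.109) or with fry. For Arntl and Dbp ApoE4 on chow was the group apart, as in the genotype comparison on chow: mean Arntl signals were 147 and 285 on chow and 132 and 152 on high-fat diet in ApoE3 and ApoE4, and those of Dbp 3648, 1925, 3500 and 3206. This did not hold for the whole clock list. Its mean lay under the ApoE3 mean on 5 of 6 ApoE4 arrays on chow and on 5 of 6 on high-fat diet, and the interaction did not call it. A few arrays do not explain the glucocorticoid shift, since 6 of 6 high-fat arrays had a higher mean of the glucocorticoid target list than the median of the chow arrays. Tissue of 1 of the 2 ApoE4 groups collected at another time of day is a candidate explanation. Between the diets in ApoE4, the 7 genes that peak with Per and Dbp had a median of 0.50 and the 3 that peak with Arntl one of -0.48, a gap of 0.976 on the log2 scale (0.0996 and -0.06 in ApoE3). The labels give no time of collection, so a shift of the clock by genotype and diet cannot be separated from it.

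Other splits of the same arrays were fitted, 100 for each comparison with the real one included. For genotype on chow (805 genes, highest other split 82), genotype on high-fat diet (2302, highest other 1302), the averaged genotype comparison (3146, highest other 742) and sex (106, highest other 2), 1 of 100 splits, the real one, called as many. These counts exceeded those of the other splits tried, and 1 in 100 is the smallest share they can give. The splits treat each array as independent, which no label states. For genotype they therefore do not exclude chance differences between animals. The real split was also the only one to call as many for diet in ApoE3 (19, highest other 2) and the averaged diet comparison (3, highest other 1), but these counts are small. A split of the ApoE4 arrays called 22, and with 1 array left out the count in ApoE3 was 0 to 74, so chance cannot be excluded there. For diet in ApoE4 (0, highest other 22) and the interaction (0, highest other 3) the real count of 0 is one that any split reaches, as 100 of 100 did, so the splits say nothing about chance there and it cannot be excluded. The split with 22 genes may reflect a structure of the samples other than diet, which was not tested.

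Single arrays stood far from the other 5 of their group in 19 of 388 tests of named genes, lists and array measures, where chance marks about 1 in 20 groups. The number given is the gap to the nearest array as a share of the group's range. In ApoE3 on chow these were the LXR target list (0.645, replicate 4), Gm9706 (0.76, replicate 3), Riok2 (0.708, replicate 3) and Zfp386 (0.67, replicate 5). In ApoE4 on chow they were the 3' to 5' ratio of Actb (0.627, replicate 3), Dok2 (0.632, replicate 5), Fbxw5 (0.667, replicate 4) and Slc20a2 (0.737, replicate 4). In ApoE3 on high-fat diet they were the interferon gamma list (0.677, replicate 5), Capn15 (0.709, replicate 6), Cd80 (0.652, replicate 1), Srebf1 (0.718, replicate 4), Tns1 (0.627, replicate 3) and Ttr (0.842, replicate 6, log2 14.64 against 14.08 to 14.17 on the other 5). In ApoE4 on high-fat diet they were the ribosomal list (0.68, replicate 2), Fam227b (0.713, replicate 2), Npm1 (0.696, replicate 2), Gbp3 (0.663, replicate 4) and Srebf1 (0.635, replicate 4).

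Effects that differed between groups were marked by a test of the difference itself. The diet effect differed between genotypes by a median of -0.2211 for the unfolded protein response list and of 0.08406 for ribosomal proteins (camera adjusted p = 0.00686 and 0.00845, and adjusted p = 0.981 for each with an estimated correlation). The genotype effect averaged over diets differed between the sexes, females minus males, by -0.1659 for complement (camera adjusted p = 0.0389), -0.2795 for cytokines (adjusted p = 1.12e-06), 0.2061 for cholesterol synthesis (adjusted p = 1.51e-06), -0.1407 for fibroblasts (adjusted p = 0.0301) and -0.2352 for myelin genes (adjusted p = 0.0389). With an estimated correlation their adjusted p was 0.17 to 0.746. The averaged diet effect differed by 0.4225 for neutrophils and monocytes (camera adjusted p = 0.000562), -0.3175 for MHC class II (adjusted p = 0.00787), 0.2421 for cholesterol synthesis (adjusted p = 2.6e-06), -0.1255 for fatty acid oxidation (adjusted p = 0.00787), -0.2958 for fibroblasts (adjusted p = 1.4e-05), -0.3036 for endothelium (adjusted p = 8.07e-06), -0.1051 for smooth muscle (adjusted p = 0.0257) and -0.2278 for neurons (adjusted p = 0.0211). With an estimated correlation their adjusted p was 0.267 to 0.462. In cholesterol synthesis genes the median diet effect was 0.017 in females and -0.23 in males.

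Single genes differed between the sexes in 2 simple comparisons by limma and in 0 genes of the averaged ones, where 303 and 452 had an unadjusted p under 0.05. Between genotypes on chow, the female minus male difference was 1.181 for Tcl1b3 (adjusted p = 0.0164, effects of -0.25 in females and -1.44 in males) and 1.502 for the clock repressor Cry1 (adjusted p = 0.0164, 0.58 and -0.92). Between diets in ApoE3 it was 2.065 for Cry1 (adjusted p = 0.000167, effects of 1.15 in females and -0.92 in males), 1.189 for Tcl1b3 (adjusted p = 0.0121), -1.524 for Cd93 (adjusted p = 0.0458), -1.203 for Cavin1 (adjusted p = 0.0284), -1.081 for Mmp2 (adjusted p = 0.0307) and 1.079 for Ddx59 (adjusted p = 0.0327). Each sex had 3 arrays per group, and these genes were chosen after their values were seen. Both comparisons use the ApoE3 chow arrays, so their results for Tcl1b3 and Cry1 are not separate. A sex difference among the ApoE3 chow arrays alone could give both. The simple comparisons without those arrays, genotype on high-fat diet and diet in ApoE4, had 0 such genes.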

How the results depend on the processing

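The fits with the hybridization controls or the 3' to 5' ratio as a covariate and the fit without the 4 arrays of lowest hybridization control signal were chosen after seeing the data, and the other alternatives before. Over all alternatives, 9392 values of named genes were compared with the reported ones. Of these, 8631 kept their side of the threshold, 545 kept the direction but no longer passed, 200 kept it and now passed, and 16 turned. A value counted as turned only where it passed in either fit. Changes of sign among values that passed in neither are within the 8631. The 9392 include values that did not pass in the reported fit. Of 387 results that passed there, 386 still passed with a pseudocount of 64 and 325 with the hybridization covariate. With quantile normalization 293 of the 387 still passed, and with the brain marker covariate 246. Of 2373 values of gene lists, which include lists not called, 2153 kept their side of the threshold by the same rule. Of the others, 131 no longer passed, 89 now passed and 0 turned. Without a filter the median of all genes was at -0.11 for genotype on high-fat diet. The correlation across genes of the genotype effects, 0.699, was 0.64 to 0.697 under 3 alternatives. The number of arrays limits the precision.

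For genotype on chow (805 genes) the count was 514 with only the arrays compared, in which fewer arrays entered, 1428 with all probe sets, a count of probe sets, and 1375 with the hybridization covariate. For genotype on high-fat diet (2302) it was 3678 with all probe sets and 1221 with the brain marker covariate, and averaged over diets (3146) it was 5245 and 1781. For diet in ApoE3 (19) it was 107 with array weights, 35 with all probe sets, 33 with the mean of probe sets and 0 with the brain marker covariate, and for diet in ApoE4 (0) it was 12 with the brain marker covariate. For the interaction (0) it was 2 with the epithelial covariate, 1 with the hybridization covariate and 1 without the 4 arrays. For diet averaged over genotypes (3) it was 7 with quantile normalization, 1 with no sex term, 24 with array weights, 5 with all probe sets, 12 with the mean of probe sets, 38 with the brain marker covariate, 9 with the epithelial covariate, 7 with the hybridization covariate, 6 with the 3' to 5' covariate and 6 without the 4 arrays. For sex (106) it was 51 without the 4 arrays. Of 47 list calls, 1 was left with an estimated correlation and 11 with fry, and 36 were left without the 4 arrays, all of them ApoE4. With the brain marker covariate 26 of 43 were left. Apart from the smaller sample and the count of probe sets, the cause was not tested.

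The replicate numbers do not pair arrays across groups: after removing group means, arrays of 1 number correlated at -0.17 to 0.26 and, within sex, at -0.19 to 0.17, and 6 of 24 arrays were most like an array of their own number. With the replicate number as a replicate block in place of sex, 799 genes were called for genotype on chow, 2285 on high-fat diet, 25 for diet in ApoE3, 0 in ApoE4, 1 for the interaction, 3121 for the averaged genotype comparison and 7 for the averaged diet comparison.

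With 1 array left out, the counts were 488 to 1076 for genotype on chow, 1739 to 2550 on high-fat diet, 2868 to 3284 averaged, 0 to 74 for diet in ApoE3, 0 to 5 in ApoE4, 0 to 1 for the interaction, 2 to 15 for averaged diet, 72 to 130 for sex and 40 to 52 for list calls. For genotype on chow the count was 525 and 522 without ApoE3 chow array 1 or 2, and 515, 488 and 488 without ApoE4 chow array 1, 2 or 4. The interaction had 1 gene without ApoE4 chow array 5 or ApoE3 high-fat array 5. Averaged diet had 15 without ApoE3 chow array 2, 14 without ApoE4 chow array 4, 9 without ApoE3 chow array 4, 8 without ApoE4 chow array 6, and 5 without ApoE3 high-fat array 4 or 5 or ApoE4 high-fat array 1 or 2. Among list calls, smooth muscle on chow was lost without ApoE3 chow array 4 (camera adjusted p = 0.0565), macrophages on chow without that array or ApoE4 chow array 4 (adjusted p up to 0.0779), and cholesterol and myelin genes for diet in ApoE3 without ApoE3 chow array 2 (adjusted p = 0.22 and 0.071). Losses also came for T and NK cells (7 arrays), MHC class I (8) and interferon gamma (5) on chow and for ribosomal genes in the interaction (3). Averaged over genotypes they came for fibroblasts (17), epithelium (11), fluid secretion (3) and MHC class I (1), and averaged over diets for ribosomal genes (8) and MHC class I (5). For diet in ApoE4 they came for cholesterol (10), fluid secretion (7), heat shock, interferon gamma and oxidative stress (6 each), neurons (2), MHC class I and fatty acid oxidation (1 each), while the type I interferon calls were never lost.

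The values that turned were Csf1 on chow without a filter (0.1928); with the mean of probe sets, on high-fat diet Col8a1 (0.07671), Ctnnb1 (0.1961), Axl (-0.1256), Atp5c1 (-0.000151) and Sdhd (-0.1774), and averaged over diets Ctnnb1 (0.1835), Axl (-0.1454), Hsp90b1 (0.129), Aplp2 (0.01568), Atp5c1 (-0.01304), Sdhd (-0.2186) and Rpl27 (-0.001716). Averaged over diets, Vsnl1 turned with the brain marker covariate (0.0387), and Lrp10 (0.009188) and Ttr (0.2713) with the hybridization covariate. The cause was not tested. For 144 results of named genes that passed, 211 other probe sets were measured. Of these, 88 passed in the same direction and 81 had that direction but did not pass. In the opposite direction 10 passed and 32 did not. Not run were the brain marker covariate for the lists that make it up (4 of the 47 calls), the other deposited table, whose values are equal, another Apoe probe set, of which there is none, the replicate block and the fit without a sex term for sex, and fits on only the arrays compared for the interaction, the averages and sex.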

Other observations

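Single genes of further groups differed between the genotypes averaged over diets, with 12 arrays each and n = 24 in the limma fit. Over all 8261 genes 1941 fell and 1205 rose in this comparison. The list counts in this section are to be read against that share, and 4 of 18 endothelial genes down is close to it. The endothelial genes Egfl7, a secreted vascular factor (-0.49 ± 0.084, adjusted p = 0.000115), Robo4 (-0.41 ± 0.096) and Ramp2 (-0.24 ± 0.067) fell in ApoE4, and 4 of 18 endothelial genes fell and 0 rose (list median -0.14, camera adjusted p = 0.328). Of the genes of glycolysis and the response to low oxygen, a list that was not called, those that fell included Pfkfb3, a regulator of glycolysis (-0.73 ± 0.18), the hexokinase Hk2 (-0.39 ± 0.11) and the collagen hydroxylase P4ha1 (-0.29 ± 0.073), and 8 of 16 fell and 1 rose (camera adjusted p = 0.328). Other probe sets of Egfl7 and P4ha1 did not pass, among them 1 of Egfl7 at 0.056 (adjusted p = 0.81) and 1 of P4ha1 at 0.24 (adjusted p = 0.101). The immediate early genes Ccn1 (-0.72 ± 0.11), Klf6 (-0.39 ± 0.081) and Ier3 (-0.37 ± 0.079) fell, as 5 of 13 did (camera adjusted p = 0.162). Single B cell genes fell, in a list that was not called: Ms4a1, which encodes the surface marker CD20, at -0.48 ± 0.12 (adjusted p = 0.00266) and the antibody heavy chain Ighm at -0.72 ± 0.22, with 4 of 7 down (camera adjusted p = 0.116). The neutrophil granule gene Ngp fell by 0.67 on the log2 scale, while S100a9 was at -0.81 ± 0.33 (adjusted p = 0.0567).

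Other groups held changes in both directions. Of 14 complement genes the receptor C3ar1 fell (-0.42 ± 0.11), and C1qa passed (adjusted p = 0.00298) but was Absent on all 6 ApoE3 chow arrays (mean signals in ApoE3 and ApoE4 293.6 and 398.9 on chow, 367.1 and 434.9 on high-fat diet). The probe set used for C1qb fell (-0.50 ± 0.18) and another was at -0.24 and passed, but 1 more was at 0.086 (adjusted p = 0.473), so its fall is uncertain (list camera adjusted p = 0.806). Of 43 genes of oxidative phosphorylation 9 rose and 3 fell (median 0.013, camera adjusted p = 0.116), with the complex III subunit Uqcrc2 at 0.25 ± 0.047 and the complex I subunit Ndufc1 at -0.20 ± 0.045. Among iron genes the ferritin heavy chain Fth1 fell (-0.15 ± 0.034), the peptide hormone gene Hamp fell (-0.86 ± 0.20) and Hfe, a regulator of iron uptake, rose (0.19 ± 0.047). In the extracellular matrix the proteoglycan gene Ogn rose (0.42 ± 0.072), and Sparc (-0.32 ± 0.084) and Col6a1 (-0.40 ± 0.11) fell, with 4 of 21 fibroblast genes up and 5 down (camera adjusted p = 0.586). Of 9 genes of cilia, the dynein Dnah5 fell (-0.40 ± 0.11), and of 16 junction genes the polarity gene Pard3 (-0.29 ± 0.070) and Tjp3 (-0.28 ± 0.074) fell (camera adjusted p = 0.769 and 0.769). Each of these lists was fixed before the data were examined and none was called.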
